A study of Mus musculus with 2 samples.

How the data were processed

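Cells of the cochlear lateral wall of mice at postnatal day 0, with the Wnt1-Cre driver and a fluorescent reporter, were dissociated with trypsin and sorted into a GFP positive and a GFP negative fraction, per the labels' protocols. Libraries were made with an Illumina TruSeq kit, per the labels' protocols. The labels give 1 sample per fraction, name 2 different reporters in the genotype field (Ai3 for GFP positive, Ai4 for GFP negative), and carry the numbers 68K and 180K in the titles without saying what they count. Reads were aligned with STAR to the mouse build mm9, per the submitters' processing notes. The aligner version, the counting tool and its use of strand, the annotation, the normalisation tool and the test are not given in the sources used here.

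The data are 1 deposited table of 4197 genes. Per the file headers, the authors give a value for the GFP negative library and an average for GFP positive cells, the fold (ratio) of the average over the GFP negative value, its log2, a p-value and an adjusted p-value. The ratio column equals the quotient of the 2 value columns. The deposited signal columns are read counts divided by a size factor: 100% of the GFP negative values are whole reads times 1 step, within a tolerance of 1e-06 reads, with a size factor of 0.958. The GFP positive averages are whole-number sums of 2 steps, so the authors averaged 2 libraries. For 100% of the averages exactly 1 pair of whole numbers fitted, within a relative tolerance of 1e-13, whereas 0.0953% of slightly altered averages had such a pair. The size factors of these libraries, called A and B, are 1.07 and 0.991. Neither is named in the table, whose column of averages carries 180K and not the 68K of the GFP positive sample's title, so the report gives the authors' mean without an SD, and reads per library serve only for depth, counting intervals and checks.

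The table is part of a longer one. The largest adjusted p-value in the authors' deposited table is 0.00986, the smallest log2 ratio in size lies just above 1, and every gene has at least 1 read on each side. The relation of the p-values to the adjusted p-values needs at least 24836 tested genes, of which the last listed one ranks about 8581. The total of listed values is therefore not the depth of a library, and the depth given is that of the listed genes. Gene IDs were matched to the reference names of GRCm38 (GENCODE M21), where 4064 were found and 133 were not, and these kept the symbol of the table. The table holds 8 symbols that a spreadsheet had turned into dates, and the IDs gave back their names. The reference was used for names and for which genes lie next to each other, and no coordinates are given because its build differs from mm9.

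Differences are log2 ratios of the authors' mean over the GFP negative value, with a pseudocount of 1. A gene counted as different in size at a fold of 4 or more with a value of at least 5 in the higher group. A scaling to the column total had been fixed for count data before the data were examined. It needs a full table, so the deposited normalised values were used as they stand, and the planned scaling was run as an alternative. No test across genes was made as a main result. Ratios carry exact binomial (Clopper-Pearson) 95% intervals from the recovered reads. The medians of 23 gene lists and 2 gene families fixed before the data were examined were compared with 10000 random lists of the same size from the listed genes, matched on mean log2 value in 20 bins, as a percentile. Members with a value of at least 1 in either group entered. The counting range of a list median is the central 95% over 1000 sets of redrawn reads. A percentile is given for lists of 3 or more listed members, and it ranks a list among genes already chosen for a difference. The text names the 15 genes with the largest log2 ratio in each direction among genes with a value of at least 5, predicted genes left out, up to 4 most abundant members and the extremes of each list, and Wnt1, Kcnj10, Kcnj13, Tyr, Dct, Sox10, Mitf, Xist and the Y-linked genes. Other genes named are further members of the fixed lists, close copies or neighbours of a named gene, or genes of the additional observations. They were picked after the values were seen. Some genes that the rule names are not reported here.

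As an alternative chosen after seeing the data, edgeR's quasi-likelihood test was run on the recovered reads of the 3 libraries. It called 4197 of 4197 listed genes at an adjusted p of 0.05 or less, 1831 higher and 2366 lower. The genes had been selected on the same libraries and the GFP negative side has 1 library, so this compares these libraries, not the conditions. In simulated data with 4197 genes and 3 libraries, 200 genes were raised 4-fold on the GFP positive side, at 1 dispersion of 0.05. The edgeR test called 93.5% of these and 0.125% of unchanged genes. Since all listed genes were chosen for a difference, 0.125% is not an error rate for them. The recovery of reads was tested on 4192 simulated means and returned both libraries for 99.98% of them. Of 200 random lists of 15 genes, 2% lay outside the central 95% of matched lists, and of 200 lists shifted by a log2 ratio of 4, 98% lay above it. Further alternatives were pseudocounts of 0.1 and 5, other floors and folds, centring on the median listed gene, rescaling without the 20 most abundant genes, library A or B alone, means in place of medians, and random lists that were not matched. The median for centring was taken over listed genes with a value of at least 5 in both groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 were used.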

Results

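The stria vascularis is the tissue of the cochlear lateral wall that secretes endolymph, and its intermediate cells are pigment cells that reach it from the neural crest. Lateral walls were taken from mice at postnatal day 0 that carried Cre recombinase driven by Wnt1, a gene of the early neural crest, together with a Cre-dependent fluorescent reporter. Dissociated cells were sorted into a GFP positive and a GFP negative fraction, and the RNA of each was sequenced. The series sets the transcripts of the neonatal intermediate cells against those of the other cells of the lateral wall.

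The labels list 1 GFP positive and 1 GFP negative sample. The table analysed here holds 4197 genes, each with a normalised read count of the GFP negative library and the authors' mean for GFP positive cells. All 4197 had an adjusted p of at most 0.00986 and a log2 ratio of at least 1 in size in the authors' deposited table, so a gene that is not listed has no value here, and its absence does not show equal levels. The steps of the mean are those of 2 libraries, here called A and B. The labels do not say whether the listed GFP positive sample is 1 of them: its title carries 68K, while the column of the mean carries 180K, the number in the title of the GFP negative sample. Listed genes held 12114107 reads in the GFP negative library, 17120511 in library A and 16584559 in library B. With 1 GFP negative library the differences have no replicate check, and the 95% intervals given with ratios cover counting error only. Log2 ratios are GFP positive over GFP negative on log2(value + 1), which understates the difference of genes with few reads.

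Transcripts of pigment cells, strial intermediate cells and glia were higher in GFP positive cells of the lateral wall. Transcripts of fibrocytes, cartilage, pericytes and red blood cells were lower. Of the 4197 genes, 1831 were higher and 2366 lower in GFP positive cells. At a difference of 4-fold or more, 761 were higher and 1549 lower. At 16-fold or more on the log2(value + 1) scale, 195 were higher and 126 lower. The median log2 ratio of listed genes with a value of at least 5 in both groups was -1.31. After centring on it the 4-fold counts became 1831 higher and 466 lower. The first count is every gene listed as higher, which the authors' limit on the log2 ratio fixed in advance.

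**Figure D1:**
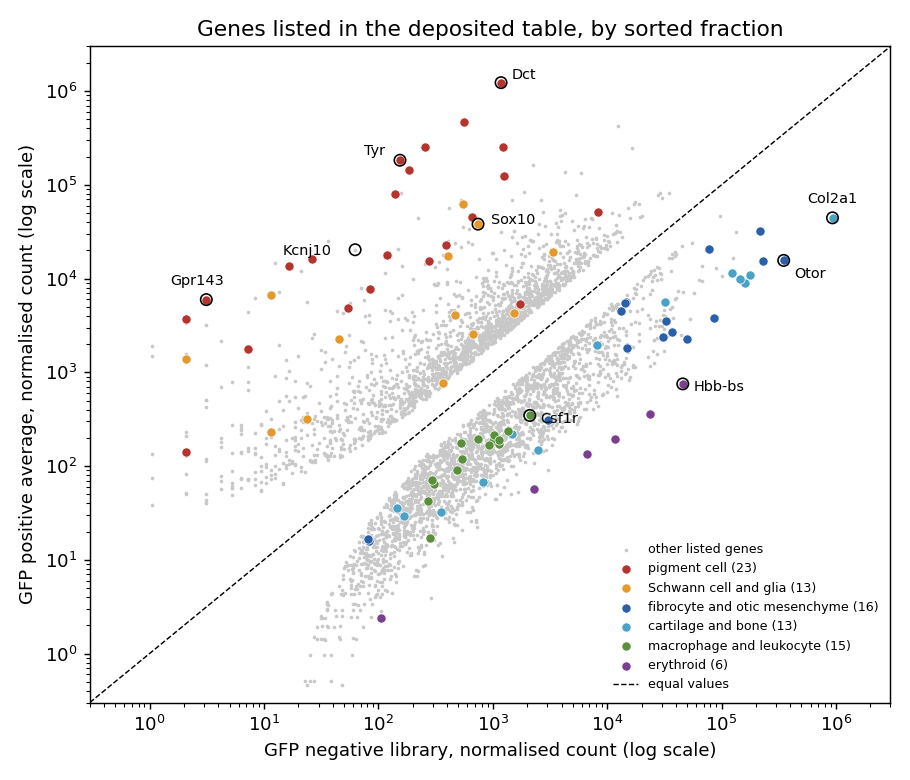
Normalised read count of the GFP negative library (horizontal, log scale) against the authors' mean for GFP positive cells (vertical, log scale) for 4197 listed genes, 1 point per gene, with 6 gene lists in colour, named genes ringed, and a dashed line at equal values. The 23 pigment cell genes all lie above the line, Dct at 1229761 against 1182, while the 16 fibrocyte genes lie below it, Otor at 15609 against 349390. The empty band along the line is where the authors' limit on the log2 ratio left out genes.

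Pigment cell transcripts were higher in GFP positive cells for all 23 listed genes of a list of 24, with 22 of them 4-fold or more higher. Their median log2 ratio was 7.68, above all 10000 random lists of listed genes matched on mean value (percentile 100). Dct, an enzyme of melanin synthesis, was the most abundant of them, at a mean of 1229761 against 1182, which is 1040-fold higher (982 to 1104). It alone made up 7.53% of the listed GFP positive values. Tyr, the rate-limiting enzyme of melanin synthesis, stood at 182804 against 155, which is 1183-fold higher (1007 to 1399). Pmel, which forms the fibrils of the melanosome, stood at 465153 against 559, and Gpnmb, a related glycoprotein, at 254423 against 257. Pmel overlaps Cdk2 on the opposite strand in the GRCm38 annotation, and reads of these 2 genes cannot be told apart where strand is not used. Ednrb, the endothelin receptor that melanoblasts need for migration and survival, was 205-fold higher (194 to 218). Mitf, the transcription factor of the melanocyte lineage, was 69.0-fold higher (63.8 to 74.7). Kit, the stem cell factor receptor of melanoblasts, showed the smallest difference of the list, with 5292 against 1728 and a log2 ratio of 1.61.

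Some pigment genes rested on very few GFP negative reads. Gpr143, a receptor of the melanosome membrane, had 3 reads there against a mean of 5960, a ratio of 1903 (651 to 9227). Tyrp1, another melanin enzyme, had 2 reads against a mean of 3665, a ratio of 1755 (486 to 14495). The melanosome trafficking list, which holds genes for the building and transport of pigment granules, had 10 higher and 1 lower among 11 listed of 22, with a median log2 ratio of 2.45 (percentile 99.9). It shares 3 listed genes with the pigment cell list. Its most abundant member was Myo5a, the motor that carries melanosomes along actin, at 46865 against 3908, followed by Rab27a at 15335 against 276. Mlph, which links these 2 proteins, was 92.6-fold higher (74.4 to 117). The lower member was Slc7a11, a cystine transporter, which was 5.78-fold lower (5.18 to 6.46).

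Strial intermediate cell genes were all higher in GFP positive cells, 12 of 12, with a median log2 ratio of 7.15 (percentile 100). The list shares 7 genes with the pigment cell list. Kcnj10, the potassium channel of intermediate cells on which the endocochlear potential depends, stood at 20292 against 63, which is 324-fold higher (252 to 425). A second inward rectifier, Kcnj13, stood at 25291 against 36.5, which is 692-fold higher (498 to 994). Met, a receptor tyrosine kinase, reached 124710 against 1263. Differences were smaller for Cd44, with a log2 ratio of 4.23, for Gsta4, a glutathione transferase, with 3.87, and for Nrp2, a semaphorin receptor, with 3.54.

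Genes of potassium and chloride transport into endolymph were higher for 6 of 7 listed members of a list of 15, with a median log2 ratio of 3.92 (percentile 100), and 2 of these are the channels Kcnj10 and Kcnj13. The gap junction genes Gjb2 and Gjb6, both known from inherited deafness, were 5.59-fold (5.45 to 5.74) and 15.99-fold (15.1 to 16.9) higher. Strial basal cell genes went both ways, with 2 higher and 4 lower among 6 listed of 8 and a median log2 ratio of -1.60 (percentile 6.41), which became -0.28 after centring. The 2 higher ones were Gjb2 and Gjb6, which stand on both lists. Cldn11, the claudin of the basal cell barrier, had a log2 ratio of -1.76, the transcription factor Tbx18 -3.78, and the junction protein Tjp1 -1.48. Of 20 marginal cell genes 2 were listed, 1 higher and 1 lower, the latter Shroom3 with a log2 ratio of -2.52, and of 7 spindle and root cell genes only P2rx2, lower with -1.64.

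Schwann cell and glial transcripts were also higher in GFP positive cells, for 13 of 13 listed genes of a list of 22, with a median log2 ratio of 4.22 (percentile 100). Redrawn reads gave medians from 3.68 to 5.24, and scaling to the listed total gave 2.99. The list shares Sox10 with the pigment cell list. Sox10, a transcription factor of both glia and melanocytes, stood at 38046 against 743, which is 51.2-fold higher (47.5 to 55.2). Erbb3, the neuregulin receptor of the Schwann lineage, was 42.4-fold higher (38.4 to 46.9). Cdh19, a cadherin of Schwann cell precursors, had the largest difference, with a mean of 6689 against 11 reads and a log2 ratio of 9.07. S100b, a calcium-binding protein of glia and melanocytes, was higher by a log2 ratio of 2.52.

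Neural crest regulators separated by gene, with 8 higher and 5 lower among 13 listed of 16 and a median log2 ratio of 1.66 (percentile 97.7). Of these genes 3 are also on the pigment cell list, 2 on the glial list, 1 on the intermediate cell list and 1 on the cartilage and bone list. The higher regulators included Pax3, with a log2 ratio of 9.58, Foxd3 with 8.81, Tfap2a with 8.73, Sox6 with 3.70 and Ets1 with 1.66. Foxd3 and Tfap2a each rested on 2 GFP negative reads, with ratios of 663 (183 to 5476) and 629 (174 to 5196). The lower ones were the mesenchymal factors Twist1, with a log2 ratio of -3.45, Snai1 with -2.91 and Snai2, the chondrocyte factor Sox9 with -2.06, and Zic1. Wnt1, whose promoter drives Cre here, was not among the listed genes.

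**Figure D2:**
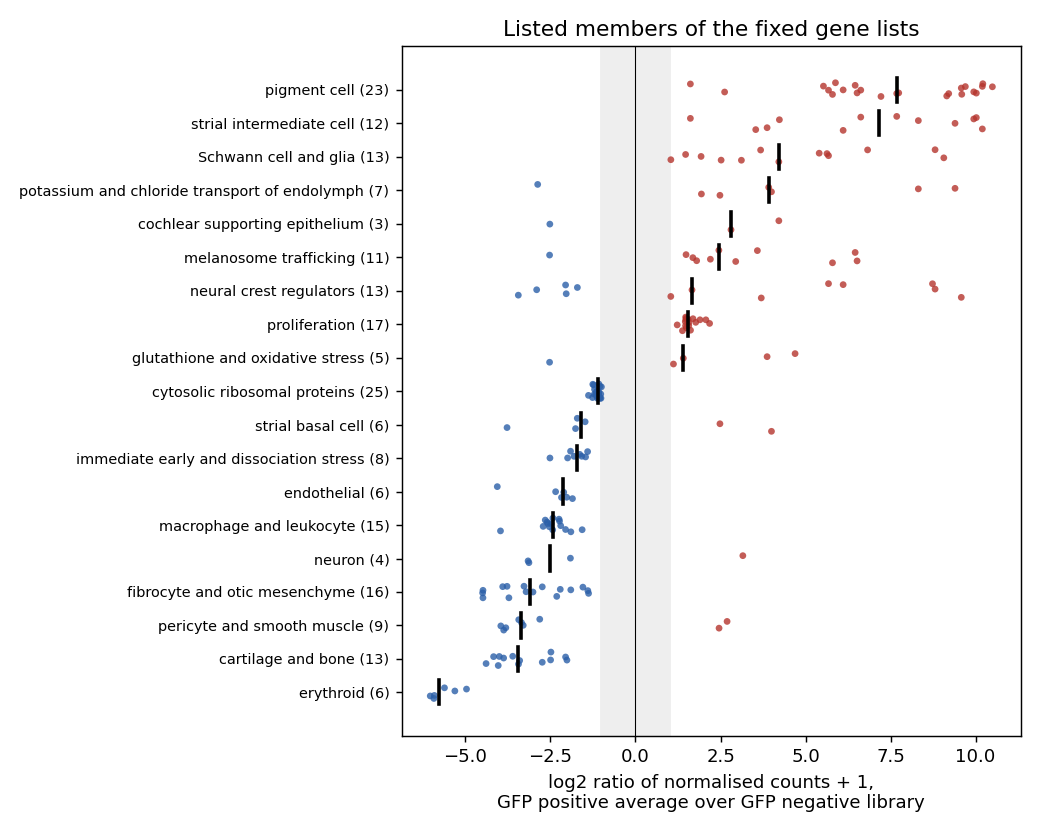
Log2 ratio of the GFP positive mean over the GFP negative library (horizontal, on normalised counts + 1) for the listed members of 19 gene lists (vertical), 1 point per gene, red if higher and blue if lower, with a black bar at each median and the number of listed members in parentheses. Medians run from 7.68 for pigment cell genes to -5.77 for erythroid genes. The grey band marks log2 ratios between the authors' limits, and the median of the ribosomal proteins turned from -1.11 to 0.21 when values were centred on the median listed gene.

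Fibrocyte and otic mesenchyme transcripts were lower in GFP positive cells for all 16 listed genes of a list of 21, 12 of them 4-fold or more, with a median log2 ratio of -3.12, below all 10000 random lists (percentile 0). Otor, a secreted protein of cochlear fibrocytes and cartilage, stood at 15609 against 349390, which is 22.4-fold lower (22.1 to 22.6). Coch, mutated in a form of inherited deafness, and Crym, a thyroid hormone-binding protein, both had a log2 ratio of -4.49. Pou3f4, a transcription factor of the otic mesenchyme, had -3.72, Car3 had -3.90 and Col1a2 had -2.74. Cartilage and bone transcripts were lower for 13 of 13 listed of 18, all 4-fold or more, with a median log2 ratio of -3.44 (percentile 0). Col2a1, the main collagen of cartilage, made up 7.38% of the listed GFP negative values, and stood at 44422 against 933668. Col9a1 and Col11a2 had log2 ratios of -4.17 and -4.01, the cartilage proteoglycan Acan -4.04 and the bone factor Runx2 -3.61. Among the 181 listed genes at 10000 or more in the GFP negative library and lower in GFP positive cells, hemoglobin left out, 0 lay under 4% of their GFP negative value and 14 at or under 6%. Of 870 lower genes between 1000 and 10000, hemoglobin again left out, 4 lay under 4%.

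Vascular and blood cell transcripts were mostly lower in GFP positive cells. Erythroid genes stood lowest, with 6 of 6 listed of 12 names lower and a median log2 ratio of -5.77 (percentile 0). Hbb-bs stood at 752 against 45834, which is 61.0-fold lower (58.0 to 64.2), and Hba-a1 at 363 against 23835, which is 65.8-fold lower (61.1 to 70.8). Both belong to near-identical gene pairs, so the split of reads within each pair is uncertain. Alas2, the heme synthesis enzyme of red cell precursors, was 40.4-fold lower (33.5 to 49.1). Pericyte and smooth muscle genes had 7 lower and 2 higher among 9 listed of 12, with a median log2 ratio of -3.35 (percentile 0.05). Pdgfrb, the receptor of pericyte growth, had a log2 ratio of -3.88 and Rgs5 had -3.81, while Cspg4 and Myh11 were higher, with 2.69 and 2.46. Endothelial genes were lower for 6 of 6 listed of 17, with a median of -2.14 that lay within the matched random lists (percentile 20.6), led by the sialomucin Emcn at 480 against 8046. Macrophage and leukocyte genes were lower for 15 of 15 listed of 17, with a median of -2.43 (percentile 6.67). Csf1r, the receptor that macrophages need to survive, stood at 346 against 2105, and Ptprc, the common leukocyte antigen, had a log2 ratio of -3.97.

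Few transcripts of neurons and of the sensory epithelium were listed. Neuronal genes had 1 higher and 3 lower among 4 listed of 15, with a median log2 ratio of -2.52 (percentile 19.2); Syt1, a synaptic vesicle calcium sensor, had -3.16, and the tubulin Tubb3 had 3.16. The hair cell genes Tmc1 and Otof, the 2 listed of 10, were lower, with log2 ratios of -3.77 and -2.68. Of 11 supporting epithelium genes 3 were listed: Sox2 and Prox1 were higher, with log2 ratios of 4.22 and 2.81, at means of 231 and 269, and Fgfr3 was lower with -2.52, giving a median of 2.81 (percentile 95.5). Sox2 also stands on the glial list. Of 10 skeletal muscle genes only Tnnt3 was listed, lower with -2.89. None of the 4 Y-linked genes, Xist or the mitochondrially encoded genes was listed.

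Cell cycle transcripts were higher in GFP positive cells for 17 of 17 listed genes of a list of 21, with a median log2 ratio of 1.55 (percentile 94.5). Of these, 15 were less than 4-fold higher. The authors' limit leaves out members with smaller log2 ratios, so the spread of the list is seen only above it. Mki67, a marker of cycling cells, stood at 17397 against 6302, which is 2.76-fold higher (2.69 to 2.84), and Top2a and Pcna had log2 ratios of 1.49 and 1.47. The largest difference was that of Rrm2, a subunit of ribonucleotide reductase, with 2.18. Immediate early and dissociation stress genes were lower for 8 of 8 listed of 19, with a median of -1.72 (percentile 3.76), which became -0.41 after centring on the median listed gene. Egr1 stood at 7329 against 41905 and Fos at 12130 against 36272. Of 20 genes of glutathione and oxidative stress, 4 were higher and 1 lower among 5 listed, with a median of 1.41 (percentile 71.3). Gstp1 and Gsta4, which conjugate glutathione, were 25.9-fold (24.9 to 26.9) and 14.6-fold (14.2 to 15.04) higher, the first with an uncertain split of reads between it and its close copy Gstp2, and Slc7a11 was the lower member.

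Cytosolic ribosomal protein genes were lower for 25 of 25 listed of 89 names, all less than 4-fold, with a median log2 ratio of -1.11 (percentile 7.62), and centring on the median listed gene turned that median to 0.21. Rplp0 and Rpl12 had log2 ratios of -1.08 and -1.38. The 15 genes with the largest log2 ratios in favour of GFP positive cells held 9 members of the pigment cell list, Kcnj13 and 5 others, which were Tspan10, Gsta2, Klhl30, Cck and Synpr. Tspan10, a tetraspanin, stood at 14703 against 12.5, and Synpr, a synaptic vesicle protein, at 6158 against 8 reads. The peptide hormone gene Cck had 1 read in the GFP negative library and a ratio of 1430 (257 to 56516), and Klhl30 had 3 reads and a ratio of 1026 (351 to 4978). Gsta2 had 2 reads and a ratio of 1597 (442 to 13192), with an uncertain split of reads between it and its close copy Gsta1.

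The 15 genes with the largest log2 ratios in favour of GFP negative cells held the 6 erythroid genes and 9 others. Among these was S100a9, a subunit of the neutrophil protein calprotectin, at a mean of 3.88 against 289, which is 74.6-fold lower (37.3 to 174). Stfa2l1, a stefin, had 1 read over both GFP positive libraries against 46, a ratio of 103 (17.6 to 4164) in favour of GFP negative cells, and Acsbg2, an acyl-CoA synthetase, had 2 against 56, a ratio of 60.3 (15.9 to 510). St8sia1, the ganglioside GD3 synthase, was 33.4-fold lower (28.8 to 38.9), the homeobox gene Msx3 32.6-fold (24.2 to 45.0) and the cartilage lectin Clec3a 31.6-fold (25.96 to 38.7). The relaxin-family receptor gene Rxfp3, the manganese transporter gene Slc30a10 and the potassium channel subunit gene Lrrc38 had log2 ratios of -4.91, -4.84 and -4.83.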

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

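The settings with library A or B alone, with a floor of 100 and with edgeR's test were chosen after the data had been seen. So was the use of the planned scaling, here to the listed total, as an alternative and not as the main setting. The pigment, fibrocyte and cell cycle lists were singled out once the medians were known. Of 190 recomputed list medians 189 kept their sign, 108 of them within the counting range and 81 beyond it. Only centring and the use of means could have reversed a sign. A pseudocount turns no ratio. The other scalings move ratios by -0.33 and -0.37, less than the authors' limit on the log2 ratio. Libraries A and B lay on the same side of the GFP negative library for every gene, so each alone kept the sign as well. The settings with all listed members and with members at 5 or more dropped no gene. They repeat the reported median of every list among the 108 and check nothing. The 1 that reversed was that of the ribosomal proteins, -1.11 as reported and 0.21 after centring on the median listed gene, a construction that takes the median of -1.31 off every log2 ratio in a table chosen for large differences. With random lists not matched on mean value their percentile went from 7.62 to 67.8, that of the cell cycle genes from 94.5 to 98.0, of the immediate early genes from 3.76 to 31.0 and of the basal cell genes from 6.41 to 35.7. With a fold of 2 in place of 4, 1830 genes were higher and 2365 lower. With a fold of 8 these counts were 395 and 706, and after centring 1831 and 466. The authors' limit on the log2 ratio fixed the counts at a fold of 2 and the higher count after centring, so these check nothing. The other settings left both counts within 1.5 times, from 515 to 771 higher and from 1367 to 1808 lower. Among them edgeR's test called every listed gene, and floors of 1, 20 and none dropped no counted gene. These repeat the main counts of 761 and 1549 and check nothing. The pigment cell median of 7.68 became 8.99 after centring and 6.72 when scaled to the listed total. That scaling moves every ratio by -0.37. The rest of the fall comes from the pseudocount of 1, which was kept while the values became smaller. A pseudocount of 5 on the deposited values gave 7.18. The fibrocyte median of -3.12 became -1.80 after centring, -3.44 without the 20 most abundant genes, -3.48 scaled to the listed total, -3.35 in library A alone, -2.88 in library B alone and -2.99 as a mean. The cell cycle median of 1.55 became 2.86, 1.22 and 1.18 under these 3 scalings, 1.47 in library A alone and 1.61 as a mean. Scaled to the listed total, the glial median of 4.22 became 2.99 and that of the supporting epithelium 2.14 from 2.81. Beyond the common shift these falls come from the kept pseudocount as well. As means, neural crest regulators had 2.55 in place of 1.66, basal cell genes -0.38 in place of -1.60, pericyte genes -2.16 in place of -3.35, neuronal genes -1.26 in place of -2.52 and supporting epithelium genes 1.502. Centring left immediate early genes at -0.41 and basal cell genes at -0.28. TMM scaling was not run, since it needs the genes that did not differ, and centring took its place. Depth limits the genes with 1 to 3 reads on a side, whose ratios span more than 10-fold. No paired analysis was possible because each fraction has 1 labelled sample.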

Other observations

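The gene families in this part, the reading of the GFP positive mean as 2 libraries, the test of a uniform carry-over, the spread used in the test of Pmel reads, the test of close neighbours without the pair that prompted it and the test of other cell types in different proportions were chosen after the values they rest on had been seen. The other tests were fixed before their result, that of counting error when the spread at a lower read limit was known. Member by member, 14 families were looked at, picked partly for the direction of members already seen, so their counts describe the listed genes and test nothing. Directions were also tallied for all symbol stems with 10 or more listed members, most of which are not reported here. All 4 listed Ifit genes, which interferon induces, were higher in GFP positive cells, among them Ifit2 at a mean of 1316 against 306 and Ifit3, whose reads are not safely split from its close copy Ifit3b, at 1349 against 16. Glutathione S-transferases were higher for 6 of 8 listed genes, led by Gsta2 and Gsta1, while Gstm5 (-1.05) and Gstt1 (-2.36) were lower and Gstm5 turned higher after centring. Subunits of the vacuolar proton pump, which acidifies lysosomes and melanosomes, were higher for 11 of 13, with a median log2 ratio of 1.84. Atp6v1a stood at 22450 against 3837 and Atp6v0c at 19797 against 4668, and the lower ones were Atp6v1b1 and Atp6v1c2. Of a set of lysosomal proteins 10 of 11 listed genes were higher, and Mcoln3, a calcium channel of endosomes and lysosomes, stood at 33820 against 617. Apart from Gstm5, these directions held under each scaling tried. The authors' limit on the log2 ratio fixed this in advance, so it checks nothing. No higher gene could turn lower, and only lower genes between about -1 and -1.31 could turn higher.

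Listed genes named for the mitochondrial respiratory chain were mostly higher, with 5 of 6 Nduf, 8 of 9 Cox and 4 of 4 Atp5 genes. They were grouped by symbol, so not all are subunits of the complex that the symbol names. Also higher were 10 of 11 sorting nexins and 13 of 16 kinesins, many of them motors of mitosis such as Kif11 (1.71) and Kif20a (1.60). These counts held under each scaling tried, but none of these genes lay where a scaling could turn it, so this checks nothing. Cathepsins went both ways, with 4 of 7 higher. Collagen genes were lower for 25 of 26 listed members, with a median log2 ratio of -2.86, and beside the cartilage and fibrocyte members these included the basement membrane chains Col4a1 (-2.69) and Col4a2 (-2.91). The exception was Col20a1 (1.80), and Col4a5 (-1.22) also turned higher after centring. Regulators of G protein signalling were lower for 10 of 12, with Rgs14 and Rgs10 higher. Cadherins were lower for 8 of 10, with Cdh19 and Cdh20 higher and Cdh13 (-1.19) turning higher after centring.

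The recovered libraries A and B lay on the same side of the GFP negative library for 4197 of 4197 genes. Both were 4-fold or more higher for 730 genes and 4-fold or more lower for 1416. The genes had been selected on the mean of these libraries and share 1 GFP negative library, so this is no independent check. Among 3876 genes with at least 40 reads over both, 46 differed 2-fold or more between A and B. All 46 were genes lower in GFP positive cells. Only Igf2 at 3772 and 8524 reads, Efemp1 at 1163 and 2504, and Agtr2 at 429 and 912 had at least 1000 reads over both. The others had fewer reads, where counting error is larger.

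Genes lower in GFP positive cells differed more between libraries A and B than higher genes. Counting error of few reads is argued against as the cause, since with at least 1000 reads the SD of log2 A over B was 0.248 for 640 lower genes and 0.111 for 1502 higher genes, a ratio of 2.22. Whether other cell types remained in the 2 sorted samples in different proportions stays open, since the result depended on the members taken, and no biological explanation was tested. Over lower members with 40 reads or more, the SD of the median log2 A over B of 7 lists was 0.235, at percentile 99.4 of sets of random lists matched on reads, but over all lower members (8 lists) the percentile was 94.0, and over all listed members 98.7. Over all listed members the medians were -0.33 for pericytes, -0.15 for neurons, -0.03 for macrophages, 0.07 for fibrocytes, 0.09 for basal cells, 0.16 for cartilage, 0.20 for endothelium and 0.35 for erythroid genes, and over lower members with 40 reads or more that of fibrocytes was -0.08.

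Some transcripts that were abundant in GFP negative cells stood at a few percent in the GFP positive mean: of 181 lower genes at 10000 or more, hemoglobin left out, 14 lay at or under a limit of 6% of their GFP negative value, such as Col2a1, Otor, Coch and Crym, the lowest at 4.43% and the median at 5.13%, and 167 lay above it. A uniform share of all GFP negative RNA, carried over during the sort, would put hemoglobin at the same level, but its median ratio was 1.64%, which is 32.0% of that of the 14 genes. Carry-over from 1 kind of GFP negative cell stays open: the SD of log2 A over B over the 14 genes was 0.153, between the bounds set for 1 common source and for several. The single values ran from -0.07 for Igfbp2 to 0.63 for Cytl1, around a median of 0.26. Expression of these genes at a low level by GFP positive cells, a biological explanation, was not tested.

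Cdk2, a cell cycle kinase, stood at a mean of 51244 against 2751, with a log2 ratio of 4.22. The gene overlaps Pmel on the opposite strand in the GRCm38 annotation, so Pmel reads might have been assigned to it, and its mean was 11.02% of that of Pmel. The log2 A over B of Cdk2 (-0.03) and Pmel (-0.16) differed by 0.127. If counting were the only error (SE 0.00935), this argues against a Cdk2 value made up only of Pmel reads. A share of Pmel reads stays open, since higher genes with at least 1000 reads vary about as much (SD 0.111). For reads reaching close neighbours in general the result depends on the denominator: of 18 other neighbours of 30 abundant genes, within 5 kb, 3 were 4-fold or more higher, a share of 0.375 (exact 95% interval 0.0852 to 0.755) of the 8 that are listed and of 0.167 (0.0358 to 0.414) of all 18 if the 10 not listed, which have no value, are taken as not higher. The 3 higher ones were Teddm2, which overlaps Glul on the opposite strand (3.34), Gstp2 next to Gstp1 (4.84) and Cfb next to C2 (4.94). Rxfp3 next to Slc45a2 goes the other way, with a log2 ratio of -4.91. Dgka also overlaps Pmel but is not listed, so it has no value and decides nothing. Expression of Cdk2 in pigment cells was not tested.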
